A study of Homo sapiens with 12 samples.

How the data were processed

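RNA was measured in 12 libraries of H1975 cells, a human non-small cell lung cancer line, each treated with 0.5 µg/ml doxycycline for 2 days to induce a short hairpin RNA. Per the labels, RNA was selected on oligo(dT) beads, fragmented RNA was reverse transcribed with random primers, and the amplified products were circularised to form the libraries. The steps named in the labels do not mark the strand of the RNA, so reads from a gene and from an antisense partner cannot be separated in these values. The groups were taken from the sample titles: control, sh-A, sh-B and sh-C, with 3 libraries each. Libraries are named by the group and the number in the title, which runs from 1 to 3 for control and sh-C and from 3 to 5 for sh-A and sh-B. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, and that spread can be technical.

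For each library the authors deposited an expected count and an FPKM value per gene, which scales fragments by transcript length and by the mapped fragments of the library. Per the submitters' processing notes, Bowtie2, HISAT and RSEM were used with the genome build hg19, and their versions, roles and settings, including strand, are not given in the sources used here. An expected count is an estimate that shares ambiguous fragments between genes, and 66.1% of the deposited expected counts above 0, which are printed to 2 decimals, were whole as printed. The lowest FPKM listed was 0.01, and 20433 genes were listed in at least 1 library, with 17033 to 18590 per library. The authors also deposited 1 table per hairpin that gives the group means as a normalised signal, the log2 ratio of knockdown to control and a probability named PPEE, and the tool behind them is not given in the sources used here. Genes are identified by NCBI gene IDs, of which 15620 were named from these comparison tables, 4734 from a RefSeq gene table of assembly GRCh38.p14 matched by the same IDs, and 79 stayed without a name. No coordinates are given, because the reference used for names is of another build than the files. The number of columns of per-sample values that matched no sample was 0.

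Expected counts were rounded to whole numbers and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with the default filter of that package, which works from a minimum count of 10, and 15592 genes remained. Libraries were scaled by the trimmed mean of M-values. One mean per group was fitted over all 12 libraries, so that the 4 groups share 1 estimate of the spread, and the median common biological coefficient of variation was 0.145. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are counts-per-million (CPM) values after scaling, computed here, and a ± gives the SD over the 3 libraries of a group. For a gene without a count in the 3 control libraries, the fold is a lower bound against a floor of 3 counts summed over the control libraries. This floor, and the interval of a ratio over 1 count, cover counting error only. The authors' PPEE values were compared with these calls at the same threshold of 0.05 but entered no test.

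The comparisons were sh-A, sh-B and sh-C with the control, sh-B with sh-C, and sh-A with the mean of sh-B and sh-C. For the comparisons with the control, 31 gene lists were fixed. The lists are NuA4/TIP60 complex subunits, other histone acetyltransferases, G1/S transition and DNA replication, G2/M and mitosis, p53 target genes, DNA double-strand break repair, MYC-driven nucleolar and ribosome biogenesis genes, epithelial identity, mesenchymal genes, receptor tyrosine kinases, output of the MAPK pathway, YAP/TEAD target genes, the TGF-beta response, interferon-stimulated genes, NF-kB targets and inflammatory cytokines, MHC class I antigen presentation, apoptosis regulators, the ATF4 stress response, the unfolded protein response, cholesterol biosynthesis, hypoxia and glycolysis, oxidative phosphorylation, lysosome and autophagy, cyclin-dependent kinase inhibitors and senescence-linked genes, heat shock and immediate early genes, alveolar and lung lineage, replication-dependent histones, cytosolic ribosomal proteins, and markers of fibroblasts, leukocytes and endothelium. The fibroblast list had too few measured members, so 30 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison. A second value with the correlation estimated from the data and the fry test were run beside it. The fry test asks whether a list moves on balance in 1 direction, while camera compares the list with the other genes, so the 2 tests answer different questions. The lists, groups, tests and the rule for naming genes were set before the data were examined. The list tests of the comparisons between hairpins were added later.

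The genes named are KAT5, AXL, EGFR, MYC and CDKN1A, and for each hairpin up to 8 rises and 8 falls with the largest fitted log2 fold change. These had to be called with an absolute log2 fold change of at least 1, reach 5 CPM in the higher group and show no overlap between the 3 values of each group, so that each such gene moved the same way in all 3 libraries. Chance gives no overlap in 10% of comparisons of 3 with 3. For the genes called with both sh-B and sh-C up to 12 per direction were named under the same conditions, and for the comparisons between hairpins 4 per direction. Genes withheld for evaluation are not reported here. Up to 4 members per list with the smallest adjusted p were eligible. Genes without a symbol, non-coding and pseudogene symbols of set patterns and sex-linked marker genes were not named. Genes called with all 3 hairpins were named after their values were seen.

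Alternatives were other size factors (RLE), DESeq2 1.42.0, no filter on low counts, a filter at 1 CPM in 3 libraries with a summed count of 100, a fit of the compared groups alone, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes at FPKM 1 or more in 3 libraries, the number in the title as a block, a fold limit, the list tests above, and each library left out in turn. Leaving out sh-A 3, sh-B 3 and sh-C 1 together was chosen after seeing the data, because each stood apart from its group. The chi-square per degree of freedom between libraries of a group was 44.52 and 59.14 for sh-A 3 with sh-A 4 and sh-A 5, against 7.86 between those. It was 34.94 and 34.69 for sh-B 3 with sh-B 4 and sh-B 5, against 3.23, and 24.44 and 18.63 for sh-C 1 with sh-C 2 and sh-C 3, against 6.63. Between control libraries it was 4.55 to 9.15. The median fold change moved by at most 0.01 on the log2 scale between the scalings.

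Depth ran from 15631504 to 28073366 expected fragments per library. The steps were tested on simulated counts drawn from the means and sizes of these libraries. Over 15398 simulated genes, the share of changed genes recovered for sh-A was 41.8%, 77.6% and 89.4% at absolute log2 changes of 0.6, 1 and 2, with 10 false calls among 149. For sh-B it was 46.3%, 73.1% and 87.9%, with 10 false calls among 148, and for sh-C 43.3%, 76.1% and 92.4%, with 6 among 162. A simulated list shifted by 0.6 on the log2 scale was called with camera for sh-C, as were 2 lists without a shift, and 0 lists were called for sh-A with none shifted. Genes were drawn independently, so this does not test lists whose members are correlated, such as interferon-stimulated genes with sh-A (estimated correlation 0.81). Only 67, 67 and 66 genes per hairpin were changed at the 3 sizes, far fewer than were called in the data. No pair of libraries in a group differed by less than sampling noise, the lowest chi-square per degree of freedom over genes with a summed count of at least 20 being 3.23. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.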

Results

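Gene expression was measured by poly-A RNA sequencing in H1975, a human lung adenocarcinoma line that grows on a mutant epidermal growth factor receptor. Doxycycline switched on a control hairpin or 1 of 3 hairpins, sh-A, sh-B and sh-C, labelled as knockdowns of KAT5 (TIP60), the catalytic subunit of the NuA4/TIP60 histone acetyltransferase complex. Each of the 4 groups had 3 libraries. The design text names sh-B and sh-C as the hairpins to be compared with the control, and sh-A appears in the sample titles and in a comparison table of its own. Expected counts summed to 22810970, 15631504 and 24228536 in control 1, 2 and 3 and to 23854019, 19279593 and 25139266 in sh-A 3, 4 and 5. They summed to 21896342, 24780051 and 22381129 in sh-B 3, 4 and 5 and to 20968576, 28073366 and 23156546 in sh-C 1, 2 and 3. The question put to the data was which transcripts change when KAT5 is depleted.

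KAT5 transcript (NCBI gene ID 10524) was lower than in every control library in all 9 libraries with a KAT5 hairpin. It stood at 31.76, 27.55 and 27.45 CPM in control 1, 2 and 3 (28.9 ± 2.46, SD, n = 3) and at 19.51, 19.96 and 18.73 CPM in sh-A 3, 4 and 5 (19.4 ± 0.626). In sh-B 3, 4 and 5 it was 14.65, 13.44 and 12.69 CPM (13.6 ± 0.988) and in sh-C 1, 2 and 3 it was 8.24, 7.3 and 8.21 CPM (7.92 ± 0.535). The transcript left was 67% of control with sh-A (95% interval 59.1% to 76.1%), 47% with sh-B (41.3% to 53.4%) and 27.3% with sh-C (23.9% to 31.2%). The log2 fold changes were -0.58 (SE 0.09, edgeR adjusted p = 0.00091), -1.09 (SE 0.09, adjusted p = 1.1e-05) and -1.87 (SE 0.1, adjusted p = 1.6e-06). The authors' deposited tables give log2 ratios of -0.58, -1.09 and -1.86. The normalised means of control and knockdown in the authors' deposited tables were 639.9 and 428.2 for sh-A, 625.7 and 293.8 for sh-B and 627 and 171.9 for sh-C.

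**Figure D1:**
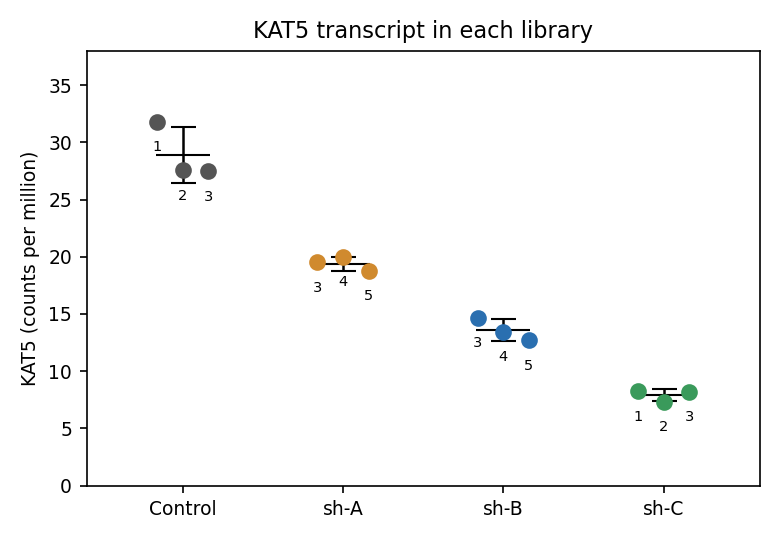
KAT5 level in each of the 12 libraries, in CPM, by group, with the group mean and SD as a line and bars. The 3 control libraries lie between 27.45 and 31.76 CPM, and the group means fall from 28.9 to 19.4, 13.6 and 7.92 CPM with sh-A, sh-B and sh-C.

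With sh-A, 14 of 25 epithelial genes fell (0 rose), 11 of 16 histone genes rose (0 fell) and 12 of 22 NF-kB targets and cytokines rose (1 fell) by edgeR. These 3 lists had adjusted p = 0.39, 0.12 and 0.39 with an estimated correlation. CDH1, which encodes the adhesion protein E-cadherin, fell by 1.94 on the log2 scale (SE 0.16, n = 3 against 3, edgeR adjusted p = 1e-05), from 713 to 185 CPM. Among the falls named for sh-A were OR51B5, an olfactory receptor gene (-4.74, SE 0.45), MMP13, a collagenase (-4.29, SE 0.28), and KRT81, a hair keratin (-3.18, SE 0.17). Their edgeR adjusted p were 2.5e-05, 1.6e-06 and 6.7e-07. ATP6V0D2, a proton pump subunit (-3.01, SE 0.27), WDR45B, an autophagy protein (-2.47, SE 0.08), and SETD9 (-2.24, SE 0.16) followed. MALL (-2.2, SE 0.21) and SAMD9L, an interferon-induced antiviral factor (-2.10, SE 0.3), came next. Without sh-A 3 the fold change of OR51B5 was -6.16. EGFR, the oncogenic receptor of this line, was lower (-0.77, SE 0.15, edgeR adjusted p = 0.0026). AXL (0.33, SE 0.26), MYC (0.12, SE 0.24) and CDKN1A (0.05, SE 0.11) did not pass the test, at edgeR adjusted p of 0.39, 0.74 and 0.77.

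The rises named for sh-A were in genes with no count in the control, or 1 count for IRS4. SLAIN1 reached 17.9 CPM, LIN28B, a regulator of let-7 microRNAs, 17 CPM, HOXD13, a homeobox gene, 16.9 CPM, and BEX4 16.1 CPM. They were at least 378, 358, 356 and 339-fold higher than control (edgeR adjusted p = 0.0012, 0.0015, 0.00098 and 0.00052). DACH1 and TBX3, developmental transcription factors, and EPB41L3 stood at 13.4, 11.4 and 12 CPM. DACH1, EPB41L3 and TBX3 were at least 282, 253 and 241-fold higher than control (edgeR adjusted p = 0.0074, 0.00074 and 0.002). IRS4, an insulin receptor substrate, reached 61.3 CPM against 1 count in the control, a ratio of 3880 with a counting interval of 697 to 153000 (edgeR adjusted p = 0.00037). These levels came mostly from 1 library. For SLAIN1, LIN28B, HOXD13 and BEX4, sh-A 3 held 5.46, 6.15, 5.08 and 6.46 times the mean of sh-A 4 and sh-A 5. For DACH1, EPB41L3, TBX3 and IRS4 it held 6.69, 6.5, 6.45 and 6.87 times that mean. Without sh-A 3 the first 7 were at least 152, 132, 151, 120, 97.2, 89.1 and 85.4-fold higher, and the ratio of IRS4 was 1310. In all, 118 genes were under 0.3 CPM in each of the other 9 libraries and averaged over 3 CPM with sh-A. Their CPM summed to 2145, 388.3 and 396.5 in sh-A 3, 4 and 5.

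**Figure D2:**
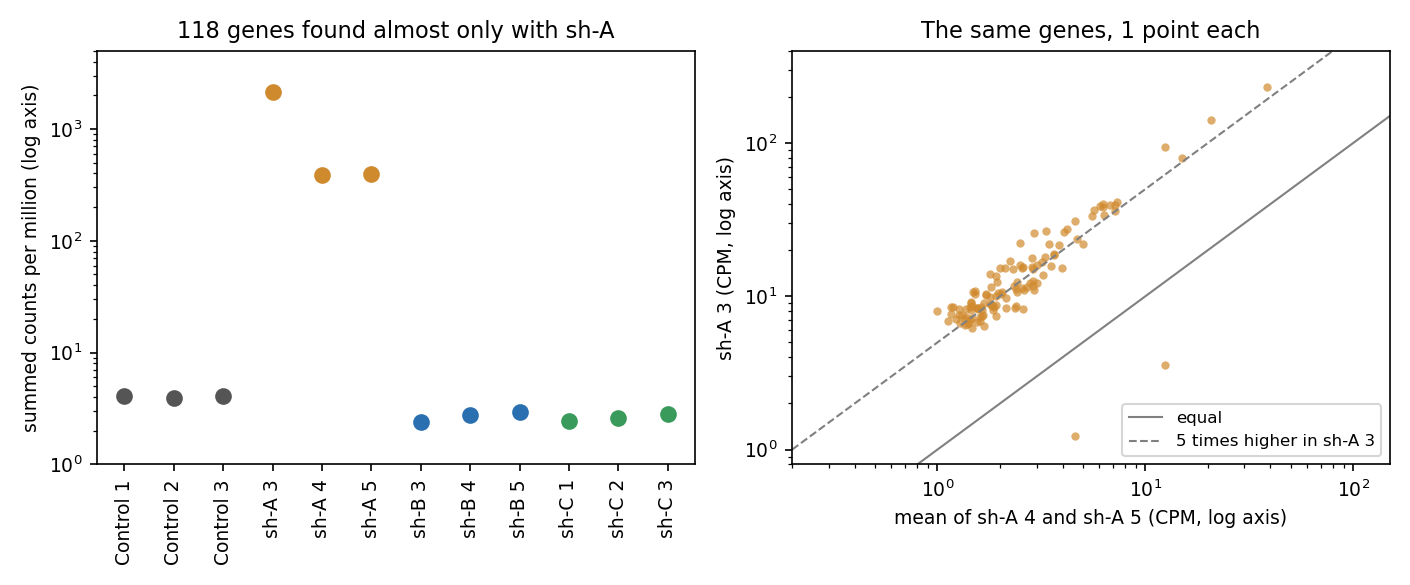
Level of each of the 118 genes in sh-A 3 (vertical axis, CPM, log scale) against the mean of sh-A 4 and sh-A 5 (horizontal axis, CPM, log scale), with lines for equal levels and for 5 times the level. Most points lie near the upper line, the median ratio being 5.34.

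Of the 25 genes of epithelial identity measured, 14 fell and 0 rose with sh-A (16 and 0 adjusted over the list alone). Their median was -0.61 (camera adjusted p = 2.1e-09, adjusted p = 0.39 with an estimated correlation). Besides CDH1, the membrane protease gene ST14 (-1.79, SE 0.17), its inhibitor SPINT1 (-1.66, SE 0.15) and the tight junction gene OCLN (-0.95, SE 0.1) fell. The list median was -1.16, -0.43 and -0.44 in sh-A 3, 4 and 5, lowest in the library that held most of the transcripts absent elsewhere. Of 16 replication-dependent histone genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 1.22 (camera adjusted p = 2.2e-09, adjusted p = 0.12 with an estimated correlation), and by library it was 0.82, 1.41 and 1.3 in sh-A 3, 4 and 5. HIST1H2AC (1.54, SE 0.17), HIST1H2BK (1.49, SE 0.12), HIST1H2BD (1.28, SE 0.12) and HIST2H2BE (0.98, SE 0.16) led them. These values are uncertain because histone genes have close copies and mostly lack a poly-A tail. Of 22 NF-kB targets and cytokines, 12 rose and 1 fell (13 and 2 adjusted over the list alone). Their median was 0.81 (camera adjusted p = 0.0013, adjusted p = 0.39 with an estimated correlation) and 0.41, 0.79 and 0.78 in sh-A 3, 4 and 5. SOD2, a mitochondrial superoxide dismutase, rose by 0.88 (SE 0.07), and the chemokine genes CXCL8 and CXCL3 by 2.08 (SE 0.33) and 2.47 (SE 0.48).

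Of 25 genes that report MAPK output, 12 fell and 4 rose with sh-A (14 and 4 adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0024, adjusted p = 0.39 with an estimated correlation). The EGFR ligand gene AREG (-1.96, SE 0.13) and the phosphatase gene DUSP5 (-0.77, SE 0.07) fell, and VGF (1.92, SE 0.15) and the ligand gene EREG (0.79, SE 0.07) rose. The list median was -0.21, -0.5 and -0.49 in sh-A 3, 4 and 5. The calls of 5 further lists depended on particular libraries, and some of them on the filter or the scaling. Among 37 interferon-stimulated genes 5 fell and 1 rose (5 and 1 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.0044, adjusted p = 0.88 with an estimated correlation). Without sh-A 3 the adjusted p was 0.53. The fry test, which asks whether the list moves and not how it compares with other genes, gave 0.21. By library the median was -1.33, -0.24 and 0.19 in sh-A 3, 4 and 5. SAMD9 (-1.07, SE 0.2) was among those that fell. Among 20 MHC class I genes 5 fell and 0 rose (4 and 0 adjusted over the list alone). Their median was -0.23 (camera adjusted p = 0.0023, adjusted p = 0.76 with an estimated correlation, 0.067 without sh-A 3). The peptide transporter gene TAP1 was at -0.74 (SE 0.11). Among 35 genes of mitosis 10 fell and 1 rose (10 and 1 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.048, adjusted p = 0.88 with an estimated correlation). The leading members were ANLN (-1.12, SE 0.09), TOP2A (-0.54, SE 0.1) and AURKA (-0.36, SE 0.08). The call was lost without control 1, control 2, sh-A 4 or sh-A 5, at up to 0.17, with other size factors (0.054) and with the stricter filter (0.079). For this list the fry test gave an adjusted p of 0.091. Among 24 p53 targets 6 rose and 2 fell (8 and 3 adjusted over the list alone). Their median was 0.26 (camera adjusted p = 0.048, adjusted p = 0.33 with an estimated correlation). BTG2 was at 2.34 (SE 0.23), FDXR at 0.68 (SE 0.13) and DDB2 at -0.41 (SE 0.08). That call was lost without control 1, control 2, sh-A 3 or sh-A 4, at up to 0.12, and with the stricter filter (0.079). Among 22 YAP/TEAD targets 5 fell and 2 rose (5 and 2 adjusted over the list alone), with WWC1 at -1.32 (SE 0.07) and AJUBA at -0.55 (SE 0.08). The test placed the list lower (camera adjusted p = 0.048, adjusted p = 0.33 with an estimated correlation), as did its median of -0.16, but its mean was 0.24. This call was lost without control 1, sh-A 4 or sh-A 5, at up to 0.12, and with the stricter filter (0.078).

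Of 15592 genes tested, 4167 (26.7%) were called with sh-A by edgeR, 2248 higher and 1919 lower. Of these 1170 changed at least 2-fold, 861 higher and 309 lower. Without sh-A 3, sh-B 3 and sh-C 1, left out together after the data were seen, 7231 genes were called.

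With sh-B, 30 of 37 interferon-stimulated genes (0 rose), 13 of 20 MHC class I genes (0 rose) and 11 of 30 mesenchymal genes (3 rose) fell, and 17 of 25 genes that report MAPK output rose (1 fell). These 4 lists had adjusted p = 0.52, 0.52, 0.26 and 0.18 with an estimated correlation. RAPGEF5, a Rap exchange factor (-5.58, SE 0.21), GJA1, the gene of a gap junction protein (-4.52, SE 0.16), and IL24, a cytokine gene (-4.39, SE 0.2), fell on the log2 scale, n = 3 against 3. Their edgeR adjusted p were 2.3e-08, 1e-08 and 7.1e-08. IRX3, a homeobox gene (-5.15, SE 0.27), STRA6, the receptor for retinol-binding protein (-5.06, SE 0.38), CFI, a complement regulator (-4.90, SE 0.52), and INPP4B, a phosphoinositide phosphatase (-4.35, SE 0.19), also fell. ALPPL2, an alkaline phosphatase with close copies and so uncertain, was at -5.99 (SE 0.77), and at -6.90 without sh-B 3. The rises were smaller. LPAR1, a lysophosphatidic acid receptor, and C9orf169 rose by 2.37 (SE 0.23) and 2.37 (SE 0.2), and SLC9A2, a sodium-proton exchanger, by 2.06 (SE 0.25). KHDRBS3 rose by 1.96 (SE 0.29), GJB2, a gap junction gene, by 1.95 (SE 0.23), and PCSK1N and FBP1, a gluconeogenic enzyme, by 1.82 (SE 0.26) and 1.82 (SE 0.14). UCHL1 rose by 1.97 (SE 0.58, edgeR adjusted p = 0.024). Its call was lost without any 1 control library or without sh-B 3, at up to 0.0816. AXL, a receptor tyrosine kinase, fell by 1.34 (SE 0.28, edgeR adjusted p = 0.0034), and EGFR rose by 0.63 (SE 0.15, adjusted p = 0.0072). CDKN1A did not pass the test (-0.06, SE 0.11, adjusted p = 0.76). MYC rose by 0.91 (SE 0.24, edgeR adjusted p = 0.012), with 914, 526 and 579 CPM in sh-B 3, 4 and 5. Without sh-B 3 its fold change was 0.63, and the call was lost without sh-B 3 or control 3, at up to 0.052.

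Of 37 interferon-stimulated genes, 30 fell and 0 rose with sh-B (31 and 0 adjusted over the list alone). Their median was -1.27 (camera adjusted p = 5.9e-14, adjusted p = 0.52 with an estimated correlation). IFI27 (-3.67, SE 0.39), the DNA sensor gene IFI16 (-1.83, SE 0.16), SAMD9 (-1.68, SE 0.21) and HERC5 (-1.36, SE 0.17) had the smallest adjusted p. Of 20 MHC class I genes, 13 fell and 0 rose (13 and 0 adjusted over the list alone). Their median was -0.37 (camera adjusted p = 0.00031, adjusted p = 0.52 with an estimated correlation). Among them were HLA-B (-1.03, SE 0.16), HLA-C (-0.76, SE 0.09) and the immunoproteasome gene PSMB9 (-1.04, SE 0.18). HLA genes share sequence with one another, so their single values are uncertain. Of 30 mesenchymal genes, 11 fell and 3 rose (13 and 3 adjusted over the list alone). Their median was -0.71 (camera adjusted p = 0.0022, adjusted p = 0.26 with an estimated correlation). The leading members were fibronectin FN1 (-1.73, SE 0.15), the collagen gene COL5A1 (-2, SE 0.2), CALD1 (-1.10, SE 0.11) and TGFBI (-1.08, SE 0.13). Of 12 alveolar and lung lineage genes, 6 fell and 2 rose (8 and 2 adjusted over the list alone). Their median was -0.77 (camera adjusted p = 0.02, adjusted p = 0.52 with an estimated correlation). The call was lost with DESeq2 (0.13) and without a filter (0.064). SOX2, a transcription factor of stem and airway cells, went from 4.07 CPM to 0.0162 CPM, near the limit of counting, and no fold is given. NAPSA, an aspartic protease of alveolar cells, fell by 2.36 (SE 0.56), and ABCA3, a surfactant lipid transporter, rose by 0.88 (SE 0.14).

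Of the 25 MAPK output genes, 17 rose and 1 fell with sh-B (17 and 1 adjusted over the list alone). Their median was 0.74 (camera adjusted p = 9.6e-08, adjusted p = 0.18 with an estimated correlation) and 0.72, 0.44 and 0.5 in sh-B 3, 4 and 5. The feedback inhibitor genes SPRY1 (1.5, SE 0.12), DUSP6 (1.49, SE 0.17) and DUSP5 (1.18, SE 0.07) rose and VGF fell by 1.95 (SE 0.15). Of 29 ATF4 targets, 13 rose and 1 fell (17 and 2 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 0.0019, adjusted p = 0.62 with an estimated correlation). Among them were the serine synthesis gene PSAT1 (1.44, SE 0.19) and the amino acid transporters SLC7A11 (1.31, SE 0.15), SLC7A5 (0.64, SE 0.1) and SLC3A2 (0.60, SE 0.09). Of 30 MYC-driven nucleolar genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.026, adjusted p = 0.94 with an estimated correlation). By library it was 0.44, 0.07 and 0.07 in sh-B 3, 4 and 5. The call of this list was lost without control 3 or sh-B 3, at up to 0.26, and the fry test gave an adjusted p of 0.19. POLR1B (0.64, SE 0.07), RRP12 (0.69, SE 0.13) and CAD (0.51, SE 0.11) rose. With sh-B 4688 of 15592 genes (30.1%) were called by edgeR, 2344 higher and 2344 lower. At least 2-fold changes were seen in 953, 176 higher and 777 lower. Without the 3 libraries that stood apart, 7388 genes were called.

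With sh-C, which left the least KAT5 transcript, MYC and 14 of 30 MYC-driven nucleolar genes rose (0 fell), and 11 of 37 interferon-stimulated genes fell (0 rose). Both lists had adjusted p = 0.57 with an estimated correlation. MYC rose by 1.80 on the log2 scale (SE 0.24, n = 3 against 3, edgeR adjusted p = 0.0028), from 358 to 1250 CPM. KLF2, a zinc finger transcription factor, rose by 2.12 (SE 0.27), DUSP1, a phosphatase that dampens MAPK signalling, by 1.97 (SE 0.38) and RHOB, a small GTPase, by 1.88 (SE 0.28), at edgeR adjusted p of 0.0024, 0.0069 and 0.0031. FOS, an immediate early gene, rose by 2.84 (SE 0.76, edgeR adjusted p = 0.026) and CTGF, a matrix-associated growth factor, by 2.23 (SE 0.6, adjusted p = 0.027). Their calls were lost without any 1 of control 1, control 2, control 3, sh-C 2 and sh-C 3, at up to 0.0966 and 0.0933. C7orf55-LUC7L2, a read-through transcript whose counts overlap those of LUC7L2 and are uncertain, was at 2.19, 14.6 and 2.37 CPM in sh-C 1, 2 and 3. It was at least 135-fold higher than control (edgeR adjusted p = 0.03), a call lost without any 1 library other than sh-C 1, at up to 0.107, and without sh-C 2 the bound was 48-fold.

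MUC1, a membrane mucin (-2.68, SE 0.49), IFI44L, an interferon-stimulated gene (-2.28, SE 0.42), SLITRK6 (-1.92, SE 0.27) and PRSS8, an epithelial serine protease (-1.82, SE 0.39), fell with sh-C. Their edgeR adjusted p were 0.0054, 0.0056, 0.0028 and 0.0099. TMPRSS4, another membrane serine protease, fell by 1.92 (SE 0.52, edgeR adjusted p = 0.027) and IFITM1, an antiviral membrane protein, by 1.81 (SE 0.56, adjusted p = 0.043). Both calls were lost when any 1 of the 6 libraries was left out, at up to 0.109 and 0.14. FYB, an adaptor of immune cells, fell by 1.79 (SE 0.43, edgeR adjusted p = 0.016), a call lost without control 2, control 3, sh-C 2 or sh-C 3, at up to 0.0817. AXL (0.23, SE 0.26), EGFR (0.03, SE 0.15) and CDKN1A (-0.02, SE 0.11) did not pass the test, at edgeR adjusted p of 0.59, 0.91 and 0.94.

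Of the 30 MYC-driven nucleolar genes, 14 rose and 0 fell with sh-C (18 and 0 adjusted over the list alone). Their median was 0.42 (camera adjusted p = 4.6e-11, adjusted p = 0.57 with an estimated correlation). Among them were SRM, which makes spermidine (0.99, SE 0.14), RRP12 (0.76, SE 0.13), the pyrimidine synthesis gene CAD (0.67, SE 0.11) and IMP4 (0.60, SE 0.09). Of 37 genes of the G1/S transition and DNA replication, 7 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.00013, adjusted p = 0.57 with an estimated correlation). The leading members were thymidylate synthase TYMS (1.06, SE 0.09) and the helicase subunit MCM2 (0.41, SE 0.08). Of the 37 interferon-stimulated genes, 11 fell and 0 rose (17 and 0 adjusted over the list alone). Their median was -0.55 (camera adjusted p = 8.3e-10, adjusted p = 0.57 with an estimated correlation). Among them were STAT2 (-0.81, SE 0.13), BST2 (-1.44, SE 0.23) and IFI16 (-0.87, SE 0.16). Of 34 genes of oxidative phosphorylation, 9 rose and 0 fell (15 and 0 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.00021, adjusted p = 0.57 with an estimated correlation), with ATP5G1 at 0.51 (SE 0.09) and SDHB at 0.43 (SE 0.09). Of 38 ribosomal protein genes, 5 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.0011, adjusted p = 0.57 with an estimated correlation).

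Of the 22 NF-kB targets and cytokines, 10 rose and 0 fell with sh-C (13 and 1 adjusted over the list alone). Their median was 0.49 (camera adjusted p = 0.00018, adjusted p = 0.57 with an estimated correlation). SOD2 was at 0.40 (SE 0.07). Of 19 heat shock and immediate early genes, 5 rose and 0 fell (9 and 1 adjusted over the list alone). Their median was 0.34 (camera adjusted p = 0.00057, adjusted p = 0.57 with an estimated correlation). KLF4, a transcription factor, was at 0.54 (SE 0.12). Of the 29 ATF4 targets, 4 rose and 2 fell (4 and 2 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.0019, adjusted p = 0.57 with an estimated correlation, fry adjusted p = 0.071). Among them were SLC3A2 (0.73, SE 0.09), SLC7A5 (0.72, SE 0.1), SHMT2 (0.51, SE 0.09) and DDIT4 (-0.42, SE 0.07). With sh-C 2643 of 15592 genes (17%) were called by edgeR, 1527 higher and 1116 lower. Changes of at least 2-fold numbered 274, 55 higher and 219 lower. A fit of the control and sh-C libraries alone called 4862 genes. The number was 766 without sh-C 2 and 6725 without the 3 libraries that stood apart.

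**Figure D3:**
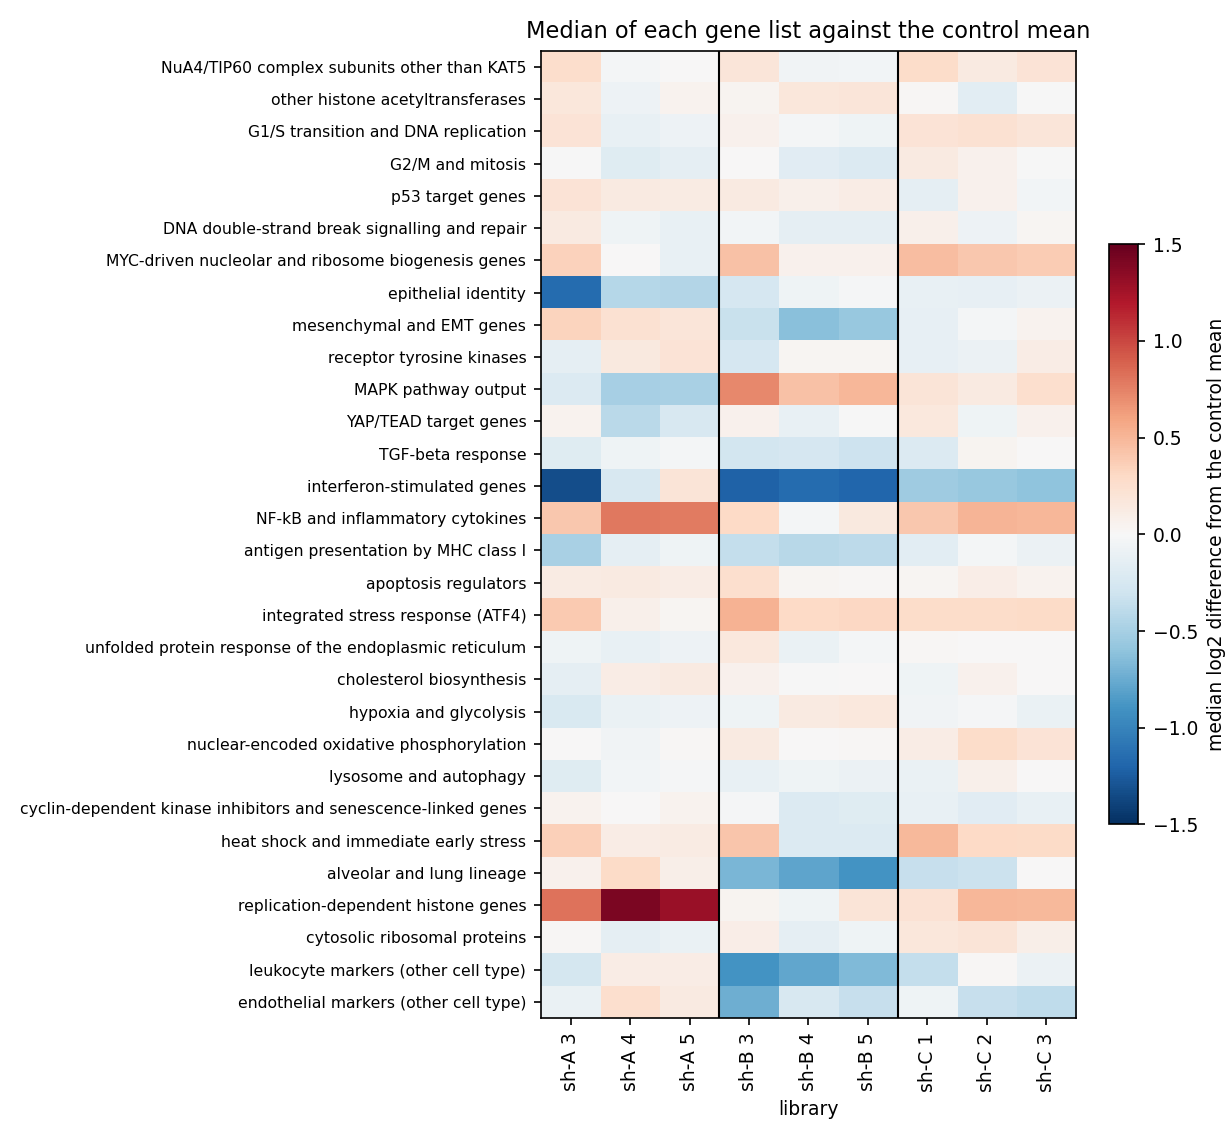
Median log2 difference from the control mean of the measured members of each gene list (rows) in each sh-A, sh-B and sh-C library (columns), shown by colour. Lists called with camera, which are not marked, number 9, 7 and 8 for the 3 hairpins. In the group fits interferon-stimulated genes have median log2 fold changes of -0.25, -1.27 and -0.55.

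The genes that moved with both sh-B and sh-C address which changes are shared between the hairpins named in the design text. On the log2 scale IFI44L fell with both, at -2.15 (SE 0.41) with sh-B and -2.28 (SE 0.42) with sh-C, as did MUC1 (-1.88, SE 0.47, and -2.68, SE 0.49) and PRSS8 (-2.90, SE 0.42, and -1.82, SE 0.39). YPEL2 (-1.92, SE 0.26, and -1.54, SE 0.25), HHIPL2 (-3.97, SE 0.35, and -1.53, SE 0.29) and SSC5D (-1.61, SE 0.27, and -1.5, SE 0.27) fell too. The edgeR adjusted p of these 6 genes ran from 1.2e-05 to 0.0096 with sh-B and from 0.004 to 0.0099 with sh-C. A further 6 genes fell with both, but their sh-C calls depended on single libraries. IFI27 (-3.67 and -1.56) and CFI (-4.90 and -1.58) lost the call without control 3, sh-C 2 or sh-C 3, at edgeR adjusted p of up to 0.0565 and 0.0858. SLPI, a secreted protease inhibitor (-3.26 and -1.5), lost it without control 3 or sh-C 3, at up to 0.0567. FYB (-1.67 and -1.79) lost it without control 2, control 3, sh-C 2 or sh-C 3, at up to 0.0817. TMPRSS4 (-2.68 and -1.92) and PADI3 (-2.37 and -1.52) lost it without any 1 of the 6 libraries, at up to 0.109 and 0.147. The rises that met the conditions were KLF2 (1.51, SE 0.27, and 2.12, SE 0.27), the lipoprotein lipase inhibitor gene ANGPTL4 (1.66, SE 0.32, and 1.5, SE 0.32) and PPIF, a mitochondrial cyclophilin (1.03, SE 0.11, and 1.04, SE 0.11). The sh-C call of ANGPTL4 was lost without control 2 or sh-C 2, at up to 0.0562. With sh-A only SSC5D among these genes was called the same way (-1.32, SE 0.27, edgeR adjusted p = 0.0036). PPIF (-0.53, SE 0.11, edgeR adjusted p = 0.0038) and PADI3 (1.75, SE 0.44, adjusted p = 0.011) were called the opposite way with sh-A. The others were not called with sh-A.

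Of the genes tested, 1158 were called the same way with sh-B and sh-C by edgeR, 676 higher and 482 lower, and 144 the opposite way. Independent lists of these sizes share 229.6 higher and 167.8 lower genes. Across genes, which are not independent replicates, the fold changes with sh-B and sh-C had a Pearson r of 0.449 and a covariance of 0.1807. In 20 simulations of unchanged groups against the same controls, r averaged 0.515 and the covariance 0.043. At most 1 gene was called in a comparison and 0 in both. With so few calls, the number shared in the simulations cannot show how far shared controls add to the sharing. The 3 control libraries do not form 2 sets of at least 2, so the control was not divided, and part of the excess over independent lists can come from the shared controls. The shared number was 2027 when each comparison was fitted with its own groups alone and 365 without sh-C 2. It was 3007 without the 3 libraries that stood apart.

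**Figure D4:**
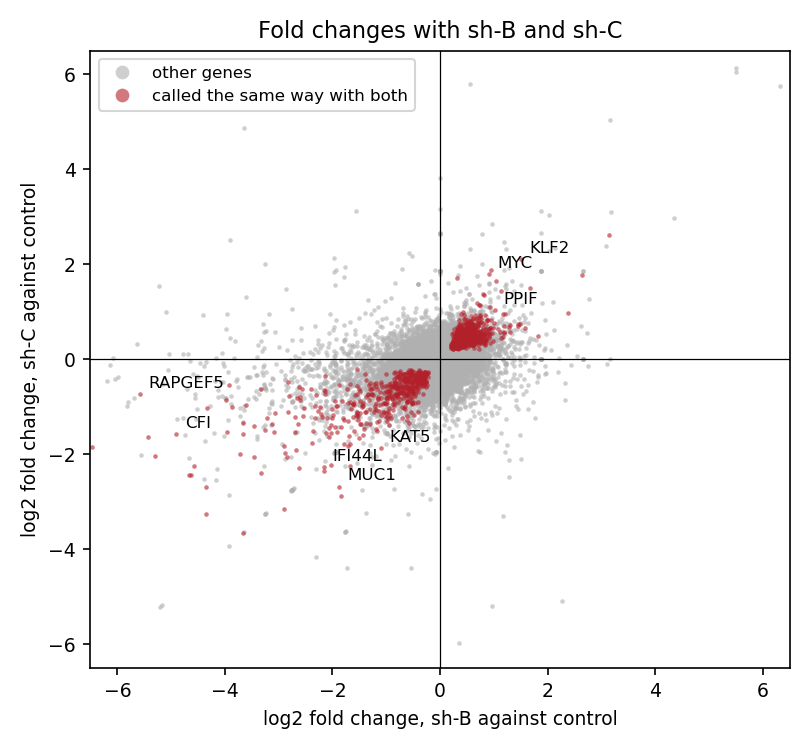
Log2 fold change with sh-C (vertical axis) against that with sh-B (horizontal axis) for the genes tested, with genes called the same way in both marked. The 1158 marked genes lie in the quadrants where both fold changes have 1 sign, and 19 genes outside the plotted range are not drawn.

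The comparison of sh-B with sh-C asks where these hairpins differ. PARP8 and MCTP1 were higher with sh-B than with sh-C by 3.07 (SE 0.14) and 3.01 (SE 0.19) on the log2 scale, n = 3 against 3. RAPGEF5 was lower (-4.85, SE 0.22). The edgeR adjusted p of these genes were 9.8e-08, 1.4e-06 and 9.8e-08. SLITRK6 (2.62, SE 0.27) and RIMKLB (2.38, SE 0.41) were higher, and ALPPL2 (-5.63, SE 0.78) and OR51B5 (-4.91, SE 0.4) lower, with ALPPL2 at -6.53 without sh-B 3. KAT5 itself was 0.78 higher with sh-B (SE 0.1, edgeR adjusted p = 0.00014) and EGFR 0.60 higher (SE 0.15, adjusted p = 0.01). AXL (-1.57, SE 0.28, edgeR adjusted p = 0.0013) and MYC (-0.89, SE 0.24, adjusted p = 0.015) were lower. The EGFR call was lost without sh-B 4 or sh-C 2, at up to 0.0533, and the MYC call without sh-B 4 or sh-B 5, at up to 0.0693. CDKN1A did not differ past the threshold (-0.04, adjusted p = 0.85).

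Between sh-B and sh-C, 13 of 25 MAPK output genes were higher and 3 lower with sh-B (16 and 5 adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00042, adjusted p = 0.37 with an estimated correlation, 0.15 without the 3 libraries that stood apart). Interferon-stimulated genes were lower with sh-B (15 lower and 2 higher of 37, 16 and 2 adjusted over the list alone, median -0.58, camera adjusted p = 0.0037, adjusted p = 0.73 with an estimated correlation). So were mesenchymal genes (13 and 3 of 30, 14 and 3 adjusted over the list alone, median -0.50, adjusted p = 0.0034, adjusted p = 0.37 with an estimated correlation). G1/S genes (13 and 1 of 37, 15 and 1 adjusted over the list alone, median -0.21, adjusted p = 0.0034, adjusted p = 0.68 with an estimated correlation) and MHC class I genes (8 and 0 of 20, 9 and 0 adjusted over the list alone, median -0.25, adjusted p = 0.0078, adjusted p = 0.68 with an estimated correlation) moved the same way. A second set was also lower with sh-B. It held genes of mitosis (13 and 3 of 35, also adjusted over the list alone, median -0.16, adjusted p = 0.022, adjusted p = 0.68 with an estimated correlation) and MYC-driven nucleolar genes (9 and 1 of 30, also adjusted over the list alone, median -0.22, adjusted p = 0.04, adjusted p = 0.73 with an estimated correlation). It held oxidative phosphorylation (10 and 0 of 34, also adjusted over the list alone, median -0.11, adjusted p = 0.022, adjusted p = 0.68 with an estimated correlation) and ribosomal proteins (7 and 0 of 38, also adjusted over the list alone, median -0.19, adjusted p = 0.01, adjusted p = 0.68 with an estimated correlation). Heat shock and immediate early genes were the last of the set (5 and 1 of 19, 6 and 1 adjusted over the list alone, median -0.39, adjusted p = 0.04, adjusted p = 0.68 with an estimated correlation). In this set the call of ribosomal proteins was lost without sh-B 4 (0.057) and that of oxidative phosphorylation without sh-B 4 or sh-C 2 (up to 0.085). Those of mitosis, nucleolar and heat shock genes were lost without sh-B 4, sh-B 5 or sh-C 1, at up to 0.085, 0.17 and 0.12. With the stricter filter the nucleolar (0.054) and heat shock (0.079) calls were lost. The edgeR fit called 4344 genes, 2024 higher and 2320 lower with sh-B, and 812 at least 2-fold, 264 higher and 548 lower. Without the 3 libraries that stood apart it called 7307.

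The comparison of sh-A with the mean of sh-B and sh-C asks whether the third hairpin resembles the others. WDR45B (-2.79, SE 0.07), SETD9 (-2.74, SE 0.15), THSD7A (-2.85, SE 0.3) and PRSS3 (-2.72, SE 0.18) were lower with sh-A, n = 3 against 6, at edgeR adjusted p of 5.6e-10, 1.4e-07, 1.5e-05 and 4.8e-07. PRSS3 is a trypsinogen gene with close copies, so its value is uncertain. AMOT, IRS4, MST4 and ALDH1A2 had fitted values of 12.86, 11.68, 11.60 and 11.40, which depend on the prior count because sh-B and sh-C were near 0. They were 11.44, 10.11, 10.09 and 9.97 without sh-A 3, and AMOT was at 14.20 without sh-B 3. KAT5 was 0.90 higher with sh-A (SE 0.08, edgeR adjusted p = 4e-06) and AXL 0.88 higher (SE 0.22, adjusted p = 0.0066). The AXL value rests largely on sh-A 3, with 52.3, 24.2 and 21.8 CPM in sh-A 3, 4 and 5. AXL was at 8.59 to 12.4 CPM in sh-B and at 29.5 to 31.8 CPM in sh-C. EGFR (-1.10, SE 0.13, edgeR adjusted p = 4.2e-05) and MYC (-1.23, SE 0.22, adjusted p = 0.00059) were lower. CDKN1A did not differ past the threshold (0.09, adjusted p = 0.49).

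Of the 25 MAPK output genes, 19 were lower and 3 higher with sh-A than with the mean of sh-B and sh-C (20 and 3 adjusted over the list alone). Their median was -0.74 (camera adjusted p = 3.3e-07, adjusted p = 0.22 with an estimated correlation). Epithelial genes were lower (13 and 3 of 25, 16 and 3 adjusted over the list alone, median -0.46, camera adjusted p = 0.00012, adjusted p = 0.71 with an estimated correlation). Histone genes were higher (12 and 0 of 16, also adjusted over the list alone, median 1.01, adjusted p = 0.00012, adjusted p = 0.31 with an estimated correlation). So were mesenchymal genes (15 and 4 of 30, also adjusted over the list alone, median 0.46, mean 1.36, adjusted p = 0.013, adjusted p = 0.31 with an estimated correlation, 0.0018 without sh-A 3) and alveolar genes (7 and 1 of 12, also adjusted over the list alone, median 0.58, mean 1.32, adjusted p = 0.018, adjusted p = 0.52 with an estimated correlation, 0.1 without a filter). Interferon-stimulated genes were higher (20 and 2 of 37, also adjusted over the list alone, median 0.50, adjusted p = 0.022, adjusted p = 0.89 with an estimated correlation), a call lost without sh-A 4 or sh-A 5, at up to 0.5. YAP/TEAD targets were placed lower by the test (10 lower and 6 higher of 22, 13 and 6 adjusted over the list alone, median -0.39, mean 0.23, adjusted p = 0.049, adjusted p = 0.31 with an estimated correlation). That call was lost without sh-A 4 or sh-A 5, at up to 0.14, and with the stricter filter (0.076). The edgeR fit called 7135 genes (45.8%), 3811 higher and 3324 lower with sh-A. It called 1845 at least 2-fold, 1458 higher and 387 lower.

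The remaining lists passed the camera test in no comparison with the control, and no direction is given for them. For sh-A, sh-B and sh-C in turn, the adjusted p was 0.46, 0.91 and 0.056 for the 17 other NuA4/TIP60 subunits and 0.59, 0.47 and 0.85 for 14 other histone acetyltransferases. It was 0.44, 0.69 and 0.78 for 29 genes of double-strand break repair and 0.75, 0.12 and 0.23 for 22 cyclin-dependent kinase inhibitors and senescence-linked genes. It was 0.46, 0.91 and 0.95 for 23 receptor tyrosine kinases, 0.39, 0.12 and 0.63 for 21 genes of the TGF-beta response and 0.44, 0.91 and 0.99 for 29 apoptosis regulators. The values were 0.44, 0.91 and 0.4 for 22 genes of the unfolded protein response and 0.78, 0.98 and 0.95 for 24 genes of cholesterol biosynthesis. They were 0.056, 0.96 and 0.13 for 31 genes of hypoxia and glycolysis and 0.25, 0.24 and 0.63 for 34 of lysosome and autophagy. Among markers of other cell types it was 0.75, 0.067 and 0.45 for 8 leukocyte genes and 0.75, 0.2 and 0.69 for 6 endothelial genes. Of 12 fibroblast markers 2 were measured well enough to test. COL1A1 was at 23.1, 19.6, 14.3 and 14.6 CPM and MFAP5 at 1.51, 0.847, 1.14 and 0.811 CPM in control, sh-A, sh-B and sh-C.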

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

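The list tests between hairpins, the tests of dependence on the amount of KAT5 transcript lost and the test of depth were chosen only after the results were seen.

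The hairpins sh-B and sh-C, each compared with the same control, differed by a test of the difference itself, and the values are given here for that reason. Between them 4344 genes differed by edgeR, KAT5 by 0.78 on the log2 scale, AXL by -1.57, EGFR by 0.60 and MYC by -0.89. PARP8 differed by 3.07, MCTP1 by 3.01, SLITRK6 by 2.62, RIMKLB by 2.38, ALPPL2 by -5.63, OR51B5 by -4.91 and RAPGEF5 by -4.85. The camera adjusted p was 0.0034 for G1/S genes, 0.022 for mitosis, 0.04 for MYC-driven nucleolar genes, 0.0034 for mesenchymal genes, 0.00042 for MAPK output, 0.0037 for interferon-stimulated genes, 0.0078 for MHC class I genes, 0.022 for oxidative phosphorylation, 0.04 for heat shock and immediate early genes and 0.01 for ribosomal proteins, and adjusted p = 0.37 to 0.73 with an estimated correlation. Of 49 other genes named for sh-A, sh-B or sh-C, 24 differed, against 27.9% of all genes tested. Most were chosen for large changes in these same libraries, so the count is no separate support. In a fit of these 6 libraries alone 4336 genes differed and the highest count in another split into 3 and 3 was 1, but only 10 splits exist, too few for a share under 0.05.

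The effect of sh-A differed from the mean effect of sh-B and sh-C by a test of the difference itself in 7135 genes, with KAT5 at 0.90, AXL at 0.88, EGFR at -1.10 and MYC at -1.23. The fitted values of AMOT, IRS4, MST4 and ALDH1A2 were 12.86, 11.68, 11.60 and 11.40, and THSD7A, WDR45B, SETD9 and PRSS3 differed by -2.85, -2.79, -2.74 and -2.72. The camera adjusted p was 0.00012 for epithelial genes, 0.013 for mesenchymal genes, 3.3e-07 for MAPK output, 0.049 for YAP/TEAD targets, 0.022 for interferon-stimulated genes, 0.018 for alveolar genes and 0.00012 for histone genes, and adjusted p = 0.22 to 0.89 with an estimated correlation. Of 50 other genes named for sh-A, sh-B or sh-C, 42 differed, against 45.8% of all genes tested. Most were chosen for large changes in these same libraries, so the count is no separate support. In a fit of these 9 libraries alone 6349 genes differed, and 1 of 100 drawn splits, the real one, gave as many, so that a split at random can be excluded as the source of the count. The highest other count was 2929, with sh-B kept whole as the reference and sh-A 5, sh-C 2 and sh-C 3 apart from sh-A 3, sh-A 4 and sh-C 1.

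Of the 861 genes at least doubled with sh-A, 575 were at least doubled in sh-A 3 over the mean of sh-A 4 and sh-A 5, with a median log2 fold change of 4.16 with sh-A. A response that follows the amount of KAT5 transcript lost is argued against for these genes by sh-C. It left less KAT5 transcript, and in it their median was 0 and their upper quartile 0.26. KAT5 protein was not measured. RNA of a HEK293-like line mixed into the sh-A libraries may be a source, as 9 of the 13 markers tested, of 16 written down before the test, were higher in sh-A 3 than in sh-A 4 and 5 and higher in every sh-A library than in all 9 others, though 8 of the 13 reach 1 CPM in the control. PAX2, too low to be tested, was at 1.56, 0.291 and 0.449 CPM in sh-A 3, 4 and 5. It met both conditions only narrowly, because control 3 was at 0.282 CPM, near the limit of counting. Among genes abundant in such cells IGF2BP1 was at 96.6, 14.9 and 18.7 CPM and CKB at 149, 72 and 74.9 CPM in sh-A 3, 4 and 5. But CKB was also at 70.7 CPM in sh-B 4, and without it 8 tested markers met both conditions. The rule written down before the test asked for over 8 markers, so it is met only with CKB. The share of all genes that meet both conditions was not counted. PEG10 was at 851, 1150 and 1280 CPM and MYCN at 0, 0.0486 and 0 CPM, and the marker SOX11 was not found among the genes listed. For the other 286 genes the median ratio of sh-A 3 to sh-A 4 and 5 after taking off the control level was 1.01, but they were chosen for less than a doubling in sh-A 3, so this value decides nothing about the mixture. A response that follows the amount of KAT5 transcript lost is argued against for them by an upper quartile of 0.49 with sh-C. The mixture, effects of this hairpin on other transcripts and differences of the cells that carry it stay open for these genes. Whether a mixture also bears on the falls with sh-A, KAT5 among them, was not tested. Of 309 genes at least halved with sh-A, 42 were at least halved in sh-A 3 against the mean of sh-A 4 and sh-A 5. The median of the epithelial list was -1.16, -0.43 and -0.44 in sh-A 3, 4 and 5.

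The libraries sh-A 3, sh-B 3 and sh-C 1 deviated from their group means in the same direction across genes (r = 0.298, 0.18 and 0.144 between sh-A 3 and sh-B 3, sh-A 3 and sh-C 1, and sh-B 3 and sh-C 1). The pattern was not confined to them. Control 2, the shallowest library, deviated with them (r = 0.156, 0.173 and 0.206), and control 3 the other way (-0.179, -0.214 and -0.172). The deviation of control 2 correlated with GC content at -0.329. The tests that follow cover sh-A 3, sh-B 3 and sh-C 1 alone. GC content correlated with the deviations, at -0.192 in the library where it did so least, but after its trend was removed r was 0.285, 0.136 and 0.115, which argues against it as the whole source, as does 0.072 for gene length. Depth is argued against as the whole source because r was at least 0.282, 0.17 and 0.13 for these pairs in 10 draws that thinned every library to the same summed count, though 2 of the 3 libraries were the shallowest of their group. With 577 genes of the sh-A pattern left out, r was 0.383 and 0.233 for sh-A 3 with sh-B 3 and with sh-C 1. This argues against the rises of those genes as the source of these 2 correlations. An effect of a mixture on the remaining genes was not removed and stays open. The r of 0.153 between sh-B 3 and sh-C 1 does not test the mixture, because neither is an sh-A library. A difference in culture or handling on 1 day could give such a pattern, but the labels name no batch, so it stays open.

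Interferon-stimulated genes were lower with sh-B and sh-C, by 1.32 and 0.72 in the mean log2 level of the list. The camera calls of the list were lost with an estimated correlation (adjusted p = 0.52 and 0.57). With sh-C the fry test gave an adjusted p of 0.086. The libraries that stood apart are argued against as the source by a median of -0.60 with sh-C without them. The other size factors moved the list by 0.006. They moved the median of all genes by at most 0.01 in any comparison, so they cannot decide on the scaling. Variation between cultures unrelated to the hairpin stays open, because the list ranged over at most 0.31 within control, sh-B or sh-C but over 1.5 in sh-A 3, 4 and 5, at 4.07, 5.1 and 5.57, and the labels name no separate cultures. A response that follows the amount of KAT5 transcript lost is argued against as the only source by the level in sh-B. That level lay at -0.60 relative to sh-C although sh-C left less KAT5 transcript. A response to KAT5 loss that differs by hairpin may remain, as may effects of the hairpins on other transcripts, and neither was tested.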

How the results depend on the processing

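Leaving out sh-A 3, sh-B 3 and sh-C 1 together was the alternative chosen only after the results were seen. KAT5 kept its direction and call under each alternative in which it was followed, except that with sh-A (-0.58) it falls short of the 2-fold limit. Under the block of title numbers KAT5 was followed with sh-C (-1.87) and not with sh-A or sh-B. With other size factors 4200, 4700 and 2654 genes were called with sh-A, sh-B and sh-C, with DESeq2 4429, 5040 and 3292, without a filter 4257, 4366 and 2233, with the stricter filter 3939, 4618 and 2693 and on log2(FPKM + 1) 3552, 4097 and 2349, a scale that shrinks the fold changes of low genes. Counting only calls of at least 2-fold gave 1170, 953 and 274. The compared groups alone gave 4862 genes and 13 lists with sh-C and 2027 shared genes, with their own estimate of the spread. With an estimated correlation 0, 0 and 0 lists were called with sh-A, sh-B and sh-C, and fry called 11 with sh-B. Without the 3 libraries together the counts were 7231 with sh-A, 7388 with sh-B, 6725 with sh-C, 7307 between sh-B and sh-C and 3007 shared. With 1 library left out they ran from 2985 to 4892, 3236 to 4299 and 766 to 2762 for the 3 hairpins, 365 to 1226 shared, 2918 to 4668 between sh-B and sh-C and 6049 to 7807 for sh-A against both. Lists ran from 6 to 9, 6 to 8 and 8 to 14, and KAT5 from -0.62 to -0.51, -1.15 to -1.02 and -1.91 to -1.80.

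The numbers in the titles were tried as a replicate block. It gave 4151, 4807 and 3621 genes with sh-A, sh-B and sh-C, 6724 for sh-A against both, 1628 shared and 10 lists with sh-C. Only number 3 joins sh-A and sh-B to the control and sh-C, and sh-A 3 and sh-B 3 stood apart from their groups. Under the block the counts with sh-A and sh-B and the shared count therefore rest on that number. That for sh-A against both does so in part, through sh-C. Same-numbered control and sh-C libraries had correlated deviations of -0.058, -0.132 and 0.13, so they share only a number. Same-numbered sh-A and sh-B libraries had 0.298, 0.12 and 0.219, but sh-A 4 correlated better with sh-B 5 (0.131).

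Directions that reversed were all of genes called in neither direction, except 1. EGFR with sh-C was -0.05 on log2(FPKM + 1), -0.06 on log2(FPKM + 0.1) and -0.09 without sh-C 3. CDKN1A between sh-B and sh-C was 0.02 and 0.03 on these scales and ran from -0.15 to 0.05 with 1 library left out, reversed without sh-B 4 (0.01) and sh-C 2 (0.05). CDKN1A with sh-C ran from -0.11 to 0.10, reversed without control 1 (0.01) and sh-C 1 (0.10), and was 0.10 without the 3 libraries. CDKN1A with sh-A was -0.01 without sh-A 4. AXL with sh-A ran from -0.19 (without sh-A 3) to 0.55 and was -0.19 without the 3 libraries. MYC with sh-A ran from -0.24 (without sh-A 3) to 0.30, and without the 3 libraries it was -0.24 at an edgeR adjusted p of 0.0104, the exception. The cause was not tested. Lists called in neither setting changed direction in 94 lists and settings, those called in 0. DESeq2 gave no adjusted p for 9 named genes. Changes below 2-fold are where depth and 3 libraries limit the calls most.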

Other observations

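The genes in the first paragraph were chosen after their values were seen, and no test here was planned for them beyond the fits above. TGFB1, which encodes the cytokine TGF-beta 1, fell by 1.18, 1.05 and 1.11 on the log2 scale with sh-A, sh-B and sh-C, SSC5D by 1.32, 1.61 and 1.5 and KRT81 by 3.18, 3.06 and 1.12. MARS2, the mitochondrial methionyl-tRNA synthetase, was higher by 0.61, 0.62 and 0.75 and HIST1H2BK by 1.49, 0.62 and 0.86, and these 5 genes stayed called with any 1 library left out. MTRNR2L2, a near copy of mitochondrial ribosomal RNA whose counts are uncertain, was at 4020, 4290 and 4650 CPM in the control, 2260, 2330 and 1010 with sh-A, 1600, 825 and 569 with sh-B and 3040, 1860 and 2160 with sh-C.

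Genes called with sh-A and sh-B went the opposite way more often than the same way, 911 against 674, while for sh-A and sh-C 687 went the same way and 211 the opposite way. Across genes the fold changes had r = -0.028 and a covariance of -0.0249 for sh-A and sh-B, and r = 0.098 and a covariance of 0.0628 for sh-A and sh-C, with 0.515 and 0.043 in simulations of unchanged groups against the same controls. Independent lists of the same sizes share 337.9 higher and 288.5 lower genes for sh-A and sh-B, of which 314 and 360 were seen, and 220.2 and 137.4 for sh-A and sh-C, of which 378 and 309 were seen. By the authors' deposited tables, 3422, 4229 and 3537 genes had a PPEE under 0.05 with sh-A, sh-B and sh-C, and 2948, 3558 and 2058 of these were called in the same direction by edgeR. The first 4 principal components of the 12 libraries held 54.7%, 16.6%, 9.7% and 6.1% of the variance.

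In fits of a hairpin and the control alone, 3371 genes were called for sh-A, 5375 for sh-B and 4862 for sh-C, and the highest count in the other splits of the 6 libraries was 0, 0 and 0. For lists the real counts were 9, 7 and 13 and the highest others 14, 10 and 14, with 7, 5 and 3 of the 10 splits giving as many as the real one. With 10 splits no share under 0.05 is possible, so the gene counts decide nothing. For lists, 6, 4 and 2 of the other splits called at least as many as the real one. The number of lists called with camera thus does not set a hairpin apart from mixed groups of these libraries. Genes called the same way with sh-B and sh-C numbered 1755 in a fit of those groups and the control, and 2 of 100 drawn splits gave as many, the real one included. This argues that the 9 libraries are not interchangeable between the groups. It does not decide how much of the sharing comes from the common control, because counts were also high with sh-B or sh-C as the common reference. The highest other count was 2294, with sh-B kept whole as the reference and control 1, control 2 and sh-C 1 apart from control 3, sh-C 2 and sh-C 3. With sh-C as the reference and the groups whole, the count was 1444.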
